A study of Mus musculus with 18 samples.

How the data were processed

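RNA from the hearts of 18 male C57BL/6 mice was sequenced as paired-end poly(A) libraries on an Illumina platform by 2 providers, with RNA extracted by TRIzol, per the labels' protocols. The groups were ISO alone, ISO with 100 nm PS and ISO with 1 µm PS, with 6 libraries each, as the titles and treatment labels give them. The provider named in the batch label was taken as the batch, with 12 libraries in batch 1 and 6 in batch 2.

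The deposited table of batch 1 gives raw counts per gene, whole numbers under Entrez gene numbers, in 46548 entries. The deposited table of batch 2 gives estimated counts per gene under Ensembl gene IDs in 57010 entries, and 19.6% of its nonzero values are not whole, so they were rounded to whole numbers. The submitters' processing notes name fastp, HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3 and DESeq2 and the builds GRCm39 and mm39, but not the role of each tool or the batch it was used for. The counter behind the batch 2 table is not given in the sources used here. Total counts per library ran from 14032257 to 22600570. Of the batch 1 entries, 215 have no gene name and hold 0.16% to 0.39% of the counts of a library, and they were left out.

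The tables were joined on genes present in both, 22146 by pairs of Entrez and Ensembl numbers in the reference gene table and 13414 by an identical symbol found once in each table, 35560 in all. The joined genes hold 85.2% to 99.5% of a library's counts. In batch 1 the share was 98.9% to 99.5%. In batch 2 it was 85.2% to 87.4% in ISO libraries and 93.1% to 95.8% in PS libraries, so the counts left out there differed between the groups. Genes in 1 table only were left out, and so were the pseudogene copies of mitochondrial genes that batch 2 lists under their own IDs, which makes mitochondrially encoded genes uncertain between batches. Genes with near-identical copies, such as ribosomal protein genes and their pseudogenes, are uncertain for the same reason, since strand and multiple mapping settings are not stated. All columns were matched to a sample. No pair among 23 pairs of libraries compared looked like a duplicate, the lowest chi-square per gene being 14.

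Counts were analysed in R 4.3.3 with edgeR 4.0.16. TMM factors scaled the libraries, filterByExpr with a minimum count of 10 kept 14623 genes, and the quasi-likelihood test (robust fit) was run on a model with group and batch over all 18 libraries, with 14 residual degrees of freedom. The contrasts were each particle size against ISO, 1 µm against 100 nm PS, and the mean of both PS groups against ISO. An adjusted p (Benjamini-Hochberg) under 0.05 counts as passed. The SE of a log2 fold change is its size divided by the square root of its F statistic. CPM are counts scaled by library size and TMM factor, and log2 CPM uses a prior count of 2. Batch values come from fits to 1 batch alone, and the batch-by-group term was tested in all libraries.

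There were 41 gene lists, 13 of them markers of other cells of the dissected heart, each with at least 5 members tested. They were tested on log2 CPM with camera of limma 3.58.1, at a preset correlation of 0.01 and again with the correlation estimated, and with fry. Members were also counted with the adjustment made over the list alone. The design, the lists, the rule for the genes to name and the alternatives listed in advance were chosen before the data were examined.

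The genes selected per comparison with ISO are the 10 largest rises and the 10 largest falls among those that passed with a mean of at least 1 CPM, a full gene symbol and the same direction in batch 1 alone. They further include the 3 genes with the smallest p in each list that passed camera and in 7 lists chosen in advance, and Nppa, Nppb, Myh6, Myh7, Acta1, Col1a1, Col3a1, Postn and Atp2a2 always. For 1 µm against 100 nm PS no gene passed, so none was named. Genes that showed a batch-by-group effect or that are named from the GC-corrected mean of both PS groups fall outside this rule and were chosen after their values were seen.

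The alternatives listed in advance were RLE and upper-quartile factors, no filter, a stricter filter (1 CPM in 6 libraries), the DESeq2 1.42.0 Wald test, limma voom with quality weights, no batch term, each batch alone, only the groups compared, the replicate number as a block, 1 surrogate variable from sva 3.50.0, an adjusted p under 0.1, a fold change of at least 2, and the removal of each library in turn. Chosen after seeing the data were the removal of ISO replicates 1 and 2 together, a correction of each library for GC content (a spline with 5 degrees of freedom fitted to the deviation from the batch mean), the same with length, the GC correction without ISO replicate 2, the same 3 ISO libraries for both sizes, and thinning to the lowest total outside mitochondrial genes (7712940 to 18579228 counts before thinning). GC content and length came from the longest GENCODE M21 transcript of each gene, which 99.8% of tested genes had. A value that changes sign where neither fit called it is counted as the same, since no direction was called. The labels do not say that replicate numbers pair the animals, so the main model has no block.

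The pipeline was tested on simulated counts with the means and library sizes of these libraries. For 100 nm PS against ISO it recovered 41% of genes changed 2-fold and 93% of genes changed 4-fold (100 genes each, 14446 tested), and for 1 µm PS 40% and 87% (14460 tested). For 1 µm against 100 nm PS it recovered 52% and 82% (14444 tested), and for the mean of both 60% and 94% (14482 tested). In 5 draws with no change it called 0 genes and 0 of 41 lists, and a list raised 1.5-fold had an adjusted p = 5.4e-12. Genes were drawn independently, so these draws cannot show list calls that arise because genes of a list vary together. A GC trend simulated in 3 ISO libraries fell from a Spearman rho of 0.61 to 0.04 after the correction, with 0 genes called before and after it. Because the comparisons with ISO share their controls, 100 draws of unchanged groups were simulated, with 1 control group shared by both comparisons. In each draw all 18 libraries, ISO included, were redrawn. Each library was the overall mean of each gene plus its scaled deviations from group and batch, with a random sign. Calls in the draws were made by limma's moderated test with a trend. Apart from these draws, the real ISO libraries were split into sets of 3. Other splits of the libraries kept the group sizes, and a further 100 kept them within each batch.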

Results

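Gene expression was measured in the hearts of 18 male C57BL/6 mice that all received isoproterenol (ISO), a beta-adrenergic agonist used to stress the heart, at 2.5 mg/kg/day under the skin for 21 days. Mice of 1 group received ISO with water by gavage, and mice of the other groups received ISO with polystyrene (PS) particles of 100 nm or of 1 µm by gavage at 50 mg/kg/day, with 6 libraries in each group. The comparisons ask what oral PS adds to the ISO-stressed heart and whether particle size matters. There were no mice without ISO, so no change can be set against an unstressed heart. A first sequencing provider (batch 1) handled 3 libraries of ISO, 5 of 100 nm PS and 4 of 1 µm PS, and a second provider (batch 2) handled 3, 1 and 2. Total counts ran from 14032257 to 22600570 per library. In both batch tables together 14623 genes had enough counts to be tested, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and with batch as a term. Adjusted p values of genes are from this test, and the values after a gene are its log2 fold change and standard error (SE).

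ISO replicates 1 and 2 held the extremes of all libraries for ribosomal protein and oxidative phosphorylation genes. ISO replicate 2 lay at 231.3 on the first principal component (54.4% of the variance). It had 13152 genes detected against 16562 to 17913 in the other ISO libraries, and took 4.81% of its counts from mitochondrial rRNA against 0.66% to 2.06%. Its mean log2 CPM was the lowest of all libraries for collagen and matrix genes (3.20) and the highest for ribosomal protein genes (10.28) and for nuclear genes of oxidative phosphorylation (10.29). It also had 795 CPM of Igtp, an interferon-induced GTPase, against 16.9 to 24.6 CPM in the other ISO libraries. ISO replicate 1 took 42.6% of its counts from mitochondrial protein-coding genes, against 15.1% to 24.2% in the other ISO libraries. It had the lowest score for ribosomal protein genes (6.90) and for oxidative phosphorylation (7.96), so that all PS libraries (7.27 to 8.06 and 8.57 to 8.90) lay within the ISO range for both. Each library's deviation from its batch mean was set against GC content across genes, which are not independent replicates. The Spearman correlation ran from -0.61 to 0.01 in ISO libraries and from 0.12 to 0.37 in PS libraries, without overlap. Genes higher in PS had a higher GC content (56.8% at 100 nm and 57.6% at 1 µm) than genes lower in PS (43.3% and 42.3%).

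**Figure D1:**
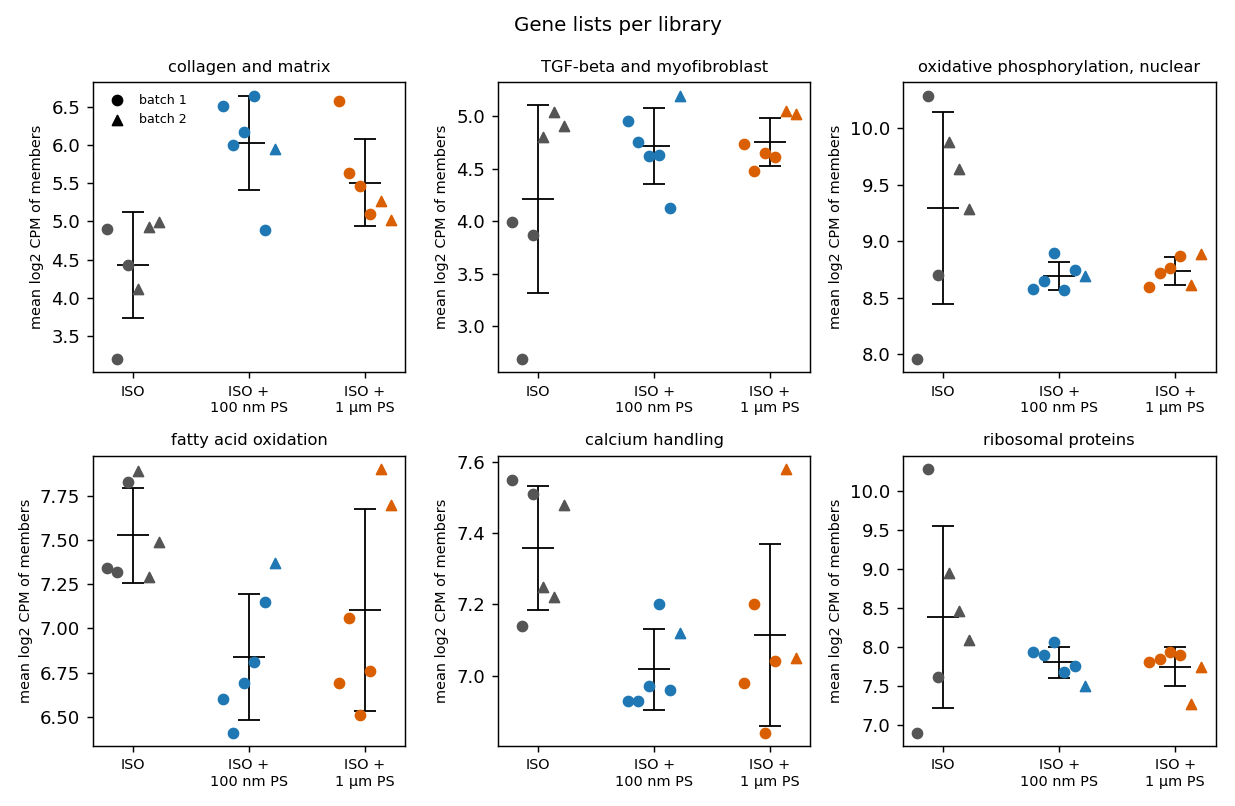
Mean log2 CPM of the genes of each list in each of the 18 libraries, by group, with 1 point per library, the shape giving the sequencing batch, and bars giving the group mean and SD (n = 6). Collagen and matrix scores lie at 3.20 to 4.99 in ISO libraries and at 4.89 to 6.64 in PS libraries, and ISO replicate 2 has the lowest collagen score and the highest ribosomal protein score (10.28).

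Hearts exposed to 100 nm PS had more RNA of the extracellular matrix than hearts with ISO alone. Col1a1, the main fibrillar collagen of scar tissue, rose from 143 ± 87.7 to 482 ± 146 CPM (mean ± SD, n = 6), a log2 fold change of 1.86 (SE 0.50, edgeR adjusted p = 0.0289). Comp rose from 4 ± 1.61 to 46.1 ± 34.3 CPM (3.06, SE 0.72, adjusted p = 0.0196). Col8a2 (3.18, SE 0.87), Ltbp2 (3.02, SE 0.71), Sfrp2 (2.53, SE 0.54), Lamc3 (2.27, SE 0.59) and Col12a1 (2.26, SE 0.69) were among the 10 largest rises. Fn1 (1.03, SE 0.21), the crosslinking enzyme Loxl1 (1.13, SE 0.23), the protease Mmp14 (0.96, SE 0.22), Col3a1 (1.19, SE 0.33) and Postn (1.56, SE 0.48), a gene of activated fibroblasts, rose as well. On log2 CPM each of these genes was higher in 6 of 6 libraries than the ISO mean of the same batch, but 100 nm PS replicate 5 lay within the CPM range of the ISO libraries for 8 of these 12 genes and above it for Col1a1, Lamc3, Loxl1 and Mmp14. Replicate 6 lay within it for 1 of them, Mmp14, and replicates 1 to 4 for 0. Of 32 collagen and matrix genes, 20 rose, none fell and 12 did not pass, and 28 rose when adjusted over the list alone. The list's median log2 fold change was 1.27, at 1.40 in batch 1 and 1.12 in batch 2. Its camera adjusted p = 3.0e-13 at the preset correlation and adjusted p = 0.733 with an estimated correlation.

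Some profibrotic signalling genes, 4 of 16, rose at 100 nm. Tgfb1 rose from 37.6 ± 9.02 to 58.6 ± 9.41 CPM (n = 6; log2 fold change 0.78, SE 0.14, adjusted p = 0.0093), Tgfb3 by 1.34 (SE 0.26, adjusted p = 0.0112) and the myofibroblast actin gene Acta2 by 1.05 (SE 0.25, adjusted p = 0.0206). In the TGF-beta and myofibroblast list 12 genes did not pass, and 6 rose when adjusted over the list alone. Its median was 0.61 (0.78 in batch 1, 0.18 in batch 2), with a camera adjusted p = 0.00105 and an adjusted p = 0.733 with an estimated correlation. Marker genes of several non-muscle cells of the heart lay higher too. Among them were Eng (0.89, SE 0.19), Esam (0.72, SE 0.22) and Vwf (1.20, SE 0.37) of endothelium. Others were Pi16 (1.10, SE 0.27), Mfap4 (1.70, SE 0.42) and Islr (0.70, SE 0.18) of fibroblasts, and Cspg4 (0.76, SE 0.16) and Notch3 (0.85, SE 0.19) of pericytes. The counts were 3 of 16 endothelial, 4 of 15 fibroblast and 4 of 14 smooth muscle and pericyte genes higher, or 4, 7 and 6 when adjusted over the list alone. Their medians were 0.50, 0.37 and 0.61, with camera adjusted p = 0.00274, 0.00744 and 0.0157. No gene passed among 9 Schwann and neuron genes (median 0.74, camera adjusted p = 0.0129), where Sox10 was at 1.47 (SE 0.53, adjusted p = 0.0837). None passed among 12 mesothelial and epicardial genes (median 1.74, camera adjusted p = 4.0e-04), where Krt18 was at 2.02 (SE 0.65, adjusted p = 0.0582). With an estimated correlation the adjusted p = 0.733 for each of these 5 cell lists. Without ISO replicate 2 the fibroblast list (0.19, adjusted p = 0.0637) and the smooth muscle list (0.43, adjusted p = 0.055) no longer passed, and the endothelial median was 0.32. The Schwann median was 1.3 without ISO replicate 1 and 0.43 without 100 nm PS replicate 1, and the mesothelial median was 2.34 without ISO replicate 5.

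Some genes of energy metabolism were lower with 100 nm PS than with ISO alone. Ndufb5 fell from 585 ± 317 to 296 ± 23.2 CPM (n = 6), a log2 fold change of -1.04 (SE 0.24, adjusted p = 0.0183). The other complex I genes Ndufs4 (-1.18, SE 0.29), Ndufv2 (-0.81, SE 0.20), mt-Nd3 (-1.43, SE 0.31) and mt-Nd1 (-0.82, SE 0.22) fell as well. Decr1 (-0.94, SE 0.23), Lpl (-0.98, SE 0.26) and the carnitine carrier Slc25a20 (-0.70, SE 0.19), which serve fatty acid use, also fell. ISO replicate 1 had 10500 CPM of Lpl against 3080 to 6050 CPM in the other ISO libraries. Of 71 nuclear genes of oxidative phosphorylation 12 fell, none rose and 59 did not pass, and 33 fell when adjusted over the list alone. Their median was -0.78 (-0.66 in batch 1, -0.99 in batch 2), with a camera adjusted p = 1.6e-10 and an adjusted p = 0.746 with an estimated correlation, and -0.32 without ISO replicate 2 (adjusted p = 0.00629). Of 33 fatty acid oxidation genes 5 fell, or 15 over the list alone. Their median was -0.62 (-0.89 in batch 1, -0.13 in batch 2), with a camera adjusted p = 6.1e-07 and an adjusted p = 0.733 with an estimated correlation. Of 13 mitochondrially encoded genes 2 fell, or 2 over the list alone (median -0.74, camera adjusted p = 0.0074, adjusted p = 0.749 with an estimated correlation). This list did not pass in batch 1 alone (-0.39, adjusted p = 0.207) or without ISO replicate 1 (-0.36, adjusted p = 0.143). Mitochondrially encoded genes have nuclear pseudogene copies, so their levels are uncertain.

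Among calcium handling genes of the cardiac myocyte, 3 of 20 fell with 100 nm PS and 17 did not pass. Trdn, which anchors the calcium store at the release channel, fell from 225 ± 71.4 to 110 ± 19.8 CPM (n = 6), a log2 fold change of -1.23 (SE 0.18, adjusted p = 0.00767). It was lower in 6 of 6 libraries, at -1.14 in batch 1 and -1.37 in batch 2. The calcium channel subunit Cacna2d1 (-1.10, SE 0.22, adjusted p = 0.0117) and the calcium pump inhibitor Pln (-0.91, SE 0.22, adjusted p = 0.0205) fell. The pump gene Atp2a2 did not pass (-0.70, SE 0.35, adjusted p = 0.191). Over the list alone 4 fell (median -0.31, camera adjusted p = 0.0019, adjusted p = 0.733 with an estimated correlation). Classical markers of cardiac stress did not pass, with Nppa at 1.36 (SE 0.67, adjusted p = 0.187), Nppb at -0.03 (SE 0.44, adjusted p = 0.972), Myh6 at 0.46 (SE 0.23), Myh7 at 0.51 (SE 0.26) and Acta1 at 0.51 (SE 0.41). In the fetal gene program only Cilp, a matrix protein of stressed hearts, rose (2.16, SE 0.57, adjusted p = 0.0281). Among 25 immediate early genes 1 rose, Jun (0.61, SE 0.19, adjusted p = 0.0459), and 0 when adjusted over the list alone. Socs3 (1.06, SE 0.34, adjusted p = 0.0547) and Zfp36 (0.84, SE 0.29, adjusted p = 0.067) did not pass. That list had a median of 0.53 (camera adjusted p = 0.0108, adjusted p = 0.746 with an estimated correlation) and did not pass in batch 1 alone (0.40, adjusted p = 0.114). Its median was 0.27 without 100 nm PS replicate 1 and 0.32 without 1 µm PS replicate 6.

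The largest falls at 100 nm rested on ISO replicate 2. Strit1, a muscle micropeptide that stimulates the calcium pump, fell by 3.43 (SE 0.75, adjusted p = 0.0156) and the interferon-induced GTPase Iigp1 by 2.60 (SE 0.57, adjusted p = 0.0158). Without ISO replicate 2 both were smaller and still passed, Strit1 at -1.54 (adjusted p = 0.0495) and Iigp1 at -0.86 (adjusted p = 0.0193). The falls of Tnnt3 (-3.16, SE 0.97), Igtp (-2.85, SE 0.82), Tnni2 (-2.39, SE 0.73), Rps29 (-2.38, SE 0.64), Ccl12 (-2.34, SE 0.67), Snhg8 (-2.27, SE 0.71) and Rps12 (-2.25, SE 0.56) did not pass without that library. They were then at 0.18, -0.01, -0.26, -0.38, -0.42, -0.35 and -0.70 in the same order. Of 45 ribosomal protein genes 10 fell, or 33 over the list alone, among them Rpl30 (-1.88, SE 0.45), Rps14 (-1.58, SE 0.40) and Rpl37 (-1.74, SE 0.46). The list's median was -1.10 (-1.09 in batch 1, -1.05 in batch 2), with a camera adjusted p = 4.8e-07 and an adjusted p = 0.806 with an estimated correlation. Without ISO replicate 2 the median was -0.29 (adjusted p = 0.298), and the 3 genes were at -0.79, -0.63 and -0.61 and did not pass. Among the largest rises, the atrial gene Myl4 (4.84, SE 1.5, adjusted p = 0.049) rested on 100 nm PS replicate 1, which had 573 CPM against 2.58 to 5.90 CPM in the rest of its group. It was at 0.60 without that library (adjusted p = 0.394) and at 5.46 without 100 nm PS replicate 6 (adjusted p = 0.0567). Without 100 nm PS replicate 1, Adamts8 went from 2.64 (SE 0.76) to 1.82 (adjusted p = 0.0942) and Dkk3, another atrial gene, from 2.54 (SE 0.77) to 1.68 (adjusted p = 0.0858). Gng8 completed the 10 largest rises (2.26, SE 0.69).

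In all 1399 genes changed with 100 nm PS, 567 higher and 832 lower, of which 456 changed at least 2-fold. Leaving out 1 library gave 170 genes (without 100 nm PS replicate 6) to 2283 (without ISO replicate 3). The count was 859 without ISO replicate 4, 493, 512, 608, 873 and 883 without 100 nm PS replicates 1 to 5, and 912 without 1 µm PS replicate 2. Of 57 genes selected by the fixed rule that passed, 8 passed whichever single library was left out (Trdn, Tgfb1, Tgfb3, Iigp1, Sfrp2, Loxl1, Cacna2d1 and Nqo1). Another 16 did not pass without 1 or 2 of the libraries, and 33 without 3 or more. After a correction of each library for GC content edgeR called 0 genes, with 2953 at an unadjusted p under 0.05, and Trdn was then at -0.82 and Col1a1 at 1.41. Without the batch term it called 0, with 2759.

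Hearts exposed to 1 µm PS had more RNA of 5 of 32 matrix genes and 4 of 14 smooth muscle and pericyte genes than hearts with ISO alone. Col18a1, a collagen of basement membranes, rose from 22.4 ± 12.7 to 48.9 ± 5.94 CPM (n = 6), a log2 fold change of 1.28 (SE 0.28, adjusted p = 0.0178). The pericyte genes Notch3 (1.02, SE 0.19, adjusted p = 0.012) and Cspg4 (0.86, SE 0.16, adjusted p = 0.012) rose. Tgfb1 (0.74, SE 0.14, adjusted p = 0.012), Tgfb3 (1.10, SE 0.25) and Acta2 (0.99, SE 0.24) rose, and so did Col6a2 (1.11, SE 0.29), Col5a1 (1.11, SE 0.30) and Loxl1 (0.80, SE 0.22). Col1a1 (1.41, SE 0.47, adjusted p = 0.0689), Col3a1 (0.77, SE 0.32, adjusted p = 0.13) and Postn (0.90, SE 0.47, adjusted p = 0.231) did not pass, and Postn was at 1.72 in batch 1 and -0.46 in batch 2. Of 32 collagen and matrix genes 5 rose, none fell and 27 did not pass, and 20 rose when adjusted over the list alone. The list's median was 0.89 (1.15 in batch 1, 0.51 in batch 2), with a camera adjusted p = 5.7e-08 and an adjusted p = 0.855 with an estimated correlation. In the TGF-beta and myofibroblast list 3 of 16 genes rose, or 5 over the list alone (median 0.44, with 0.82 in batch 1 and 0.27 in batch 2, camera adjusted p = 0.00349). Of the pericyte list, 4 of 14 smooth muscle and pericyte genes rose, or 6 over the list alone (median 0.63, camera adjusted p = 0.00442). Eng (0.72, SE 0.18) was the only endothelial gene of 16 to pass, also over the list alone (median 0.36, camera adjusted p = 0.0267), and none of 12 mesothelial and epicardial genes did (median 1.01, camera adjusted p = 0.00522). The adjusted p = 0.855 with an estimated correlation for each of these 4 lists. The endothelial list did not pass without ISO replicate 3 (0.37, adjusted p = 0.119), ISO replicate 6 (0.36, adjusted p = 0.0644), 1 µm PS replicate 3 (0.28, adjusted p = 0.0613) or 1 µm PS replicate 6 (0.36, adjusted p = 0.0909), and its median was 0.22 without ISO replicate 2. The mesothelial list did not pass without ISO replicate 3 (0.76, adjusted p = 0.0533), and was at 0.62 without ISO replicate 2 and 1.82 without ISO replicate 5.

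Several of the energy and calcium genes that fell at 100 nm also fell at 1 µm. Trdn fell from 225 ± 71.4 to 104 ± 27.3 CPM (n = 6), a log2 fold change of -1.24 (SE 0.17, adjusted p = 0.00743), with -1.12 in batch 1 and -1.42 in batch 2. Cacna2d1 (-0.91, SE 0.22), Pln (-0.72, SE 0.21), Ndufs4 (-1.16, SE 0.28), Ndufb5 (-0.97, SE 0.24), Ndufa4 (-1.32, SE 0.32), mt-Nd3 (-1.63, SE 0.30, adjusted p = 0.0124) and mt-Nd1 (-0.81, SE 0.21) fell. Among genes of fatty acid use, Decr1 (-0.87, SE 0.23), the fatty acid transporter Cd36 (-0.80, SE 0.23) and Lpl (-0.86, SE 0.25) fell. ISO replicate 1 had 10500 CPM of Lpl (3080 to 6050 in the other ISO libraries) and 2990 CPM of Cd36 (802 to 1730). The call of Lpl ended without any 1 of 15 libraries and that of Cd36 without any 1 of 13, ISO replicate 1 among them. Slc25a20 did not pass (-0.42, adjusted p = 0.158) and was at -0.77 in batch 1 and 0.04 in batch 2. Of 71 oxidative phosphorylation genes 11 fell, or 37 over the list alone. Their median was -0.76 (-0.62 in batch 1, -0.96 in batch 2), with a camera adjusted p = 2.1e-10, and -0.32 without ISO replicate 2 (adjusted p = 0.00547). Of 13 mitochondrially encoded genes 2 fell, or 3 over the list alone (median -0.72, camera adjusted p = 0.00402), and the list did not pass without ISO replicate 1 (-0.47, adjusted p = 0.0816). Of 33 fatty acid oxidation genes 3 fell, also over the list alone (median -0.42, camera adjusted p = 5.4e-04), but the list's median was -0.87 in batch 1 and 0.13 in batch 2. Calcium handling had 3 of 20 genes lower, also over the list alone (median -0.30, with -0.44 in batch 1 and 0.02 in batch 2, camera adjusted p = 0.00963). The list did not pass without ISO replicate 1 (-0.18, adjusted p = 0.0672) or ISO replicate 3 (-0.25, adjusted p = 0.0547). The adjusted p = 0.855 with an estimated correlation for each of these 4 lists. Stress markers did not pass, with Nppa at 0.48 (SE 0.62), Nppb at -0.17 (SE 0.44), Myh6 at 0.62 (SE 0.22, adjusted p = 0.0834), Myh7 at 0.70 (SE 0.24, adjusted p = 0.0767), Acta1 at 0.62 (SE 0.41) and Atp2a2 at -0.29 (SE 0.34).

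The immediate early genes Jun (0.78, SE 0.18, adjusted p = 0.0193) and Maff (0.70, SE 0.21, adjusted p = 0.0464) rose with 1 µm PS, 2 of 25 genes of their list, also over the list alone. The list's median was 0.57 (camera adjusted p = 0.00522, adjusted p = 0.855 with an estimated correlation). It was 0.08 in batch 1 and 0.88 in batch 2, and was 0.16 without 1 µm PS replicate 6 (adjusted p = 0.176). The 10 largest rises were Lamc3 (1.91, SE 0.57), Susd2 (1.65, SE 0.42), the joint lubricant gene Prg4 (1.47, SE 0.38), Col16a1 (1.37, SE 0.38), Col18a1, Srcap (1.27, SE 0.36), Alpl (1.26, SE 0.29), Ier5l (1.24, SE 0.34), Tmem200b (1.22, SE 0.25) and Ahnak2 (1.21, SE 0.32). The largest falls were those of Strit1 (-3.43, SE 0.76, adjusted p = 0.0184) and the chemokine Ccl12 (-2.47, SE 0.69). They were followed by Iigp1 (-2.37, SE 0.57), Clec2d (-2.29, SE 0.59), Rps29 (-2.17, SE 0.64), Rps12 (-2.13, SE 0.55), Zfp993 (-2.11, SE 0.54), Rps27 (-2.10, SE 0.57), Rpl37rt (-2.06, SE 0.51) and Rpl6l (-2.05, SE 0.58). Without ISO replicate 2, Strit1 (-1.90, adjusted p = 0.0165), Iigp1 (-0.86, adjusted p = 0.0164) and Rpl37rt (-0.74, adjusted p = 0.0265) still passed, while Ccl12 (-0.88), Clec2d (-0.78), Rps29 (-0.39), Rps12 (-0.73), Rps27 (-0.64) and Rpl6l (-0.30) did not. Strit1 was at -4.26 without 1 µm PS replicate 6. Of 45 ribosomal protein genes 11 fell, or 36 over the list alone. Their median was -1.08 (-1.09 in batch 1, -1.10 in batch 2), with a camera adjusted p = 1.8e-08 and an adjusted p = 0.855 with an estimated correlation. Without ISO replicate 2 the median was -0.38 (adjusted p = 0.0314), with Rps14 (-1.55, SE 0.40), Rpl30 (-1.72, SE 0.44) and Rpl37 (-1.68, SE 0.44) then at -0.71, -0.73 and -0.68 and not passing.

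In all 1081 genes changed with 1 µm PS, 423 higher and 658 lower, of which 297 changed at least 2-fold. Leaving out 1 library gave 265 genes (without 1 µm PS replicate 1) to 2334 (without ISO replicate 3). The count was 1689, 1983, 412 and 585 without ISO replicates 1, 2, 4 and 6, 692 and 710 without 100 nm PS replicates 3 and 6, and 510, 290, 398 and 588 without 1 µm PS replicates 2, 3, 4 and 6. Of 49 named genes that passed, 9 passed whichever single library was left out (Trdn, Tgfb1, Col18a1, Cspg4, Jun, Notch3, Prdx1, Tmem200b and mt-Nd3). Another 3 did not pass without 1 or 2 of the libraries and 37 without 3 or more. After the GC correction edgeR called 0 genes, with 2349 at an unadjusted p under 0.05. Without the batch term it called 0, with 2358, and with only the ISO and 1 µm PS libraries in the fit it called 0, with 2701.

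**Figure D2:**
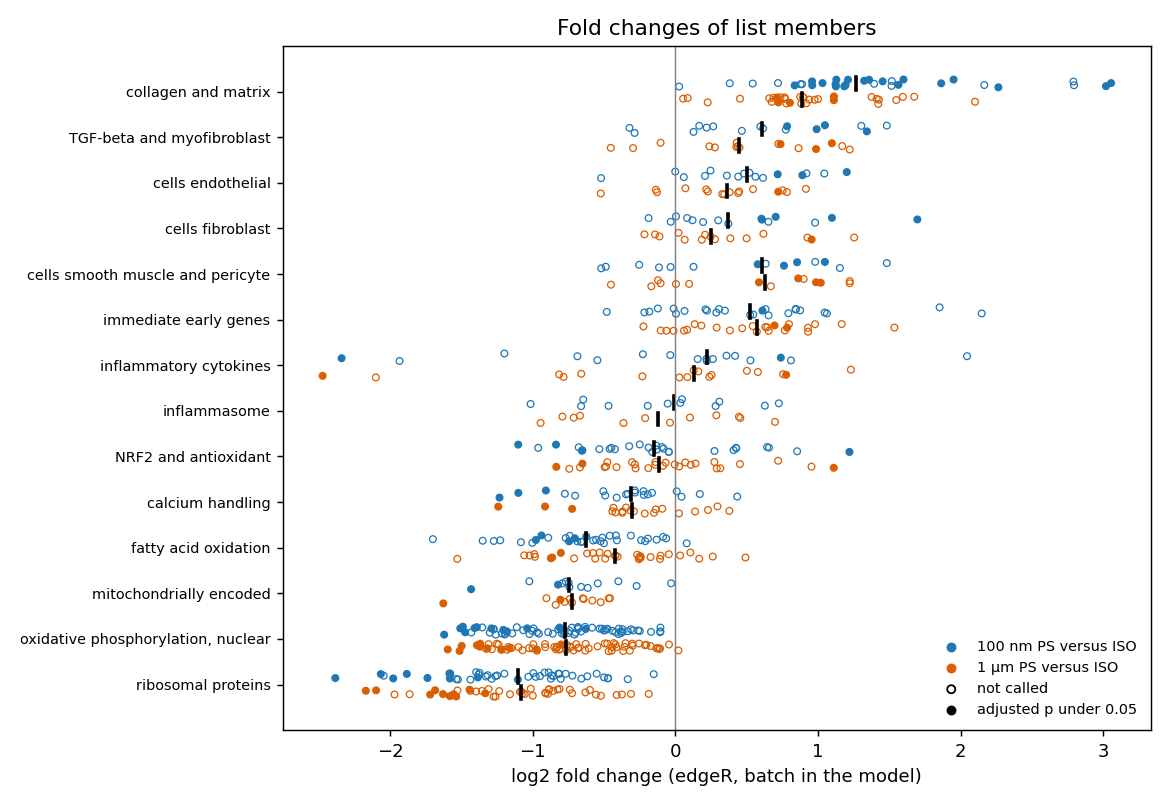
Log2 fold change against ISO of each tested member of 14 lists (1 point per gene) for 100 nm PS and 1 µm PS, with filled points for genes at an adjusted p under 0.05, open points for the others and black ticks for list medians. Collagen and matrix genes centre on 1.27 and 0.89, and oxidative phosphorylation genes centre on -0.78 and -0.76.

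Genes of inflammation, antioxidant defence and cell death did not pass as groups at either size. Of 17 inflammatory cytokine genes Nfkb2 rose at 100 nm (0.74, SE 0.20, adjusted p = 0.0308) and at 1 µm (0.78, SE 0.19, adjusted p = 0.0262), and Ccl12 fell at both. The list's medians were 0.22 (mean -0.07, camera adjusted p = 0.79) and 0.13 (camera adjusted p = 0.901). None of 12 inflammasome genes passed (-0.01 with adjusted p = 0.819, and -0.12 with adjusted p = 0.558), with Gsdme at -0.66 (SE 0.23) and -0.67 (SE 0.22). The NRF2 and antioxidant list had medians of -0.15 (adjusted p = 0.309) and -0.11 (adjusted p = 0.558). In it Prdx1 fell at both sizes (-0.65, SE 0.15 in each), Nqo1 fell at 100 nm (-1.10, SE 0.25) and Txn1 at 1 µm (-0.83, SE 0.25), while extracellular Sod3 rose at both (1.22, SE 0.33, and 1.11, SE 0.32). The fetal gene program had medians of 0.60 (adjusted p = 0.0616) and 0.55 (adjusted p = 0.122), and passed without ISO replicate 2 (0.80 with adjusted p = 0.00952, and 0.73 with adjusted p = 0.0261). In 1 µm PS the fibroblast (0.25, adjusted p = 0.0542) and Schwann lists (0.48, adjusted p = 0.106) did not pass.

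The remaining lists passed in neither comparison with ISO, and each pair of values gives the camera adjusted p at 100 nm and at 1 µm. Among immune and stress lists these were interferon response (0.613, 0.251), antigen presentation (0.41, 0.683), unfolded protein response (0.627, 0.929) and heat shock (0.273, 0.988). Among lists of cell death and signalling they were p53 and apoptosis (0.833, 0.929), ferroptosis and iron (0.555, 0.558), beta-adrenergic signalling (0.79, 0.975), xenobiotic response (0.833, 0.798), glucocorticoid response (0.79, 0.737) and circadian clock (0.833, 0.558). Among metabolic and structural lists they were glycolysis (0.631, 0.167), cardiac ion channels (0.79, 0.929), sarcomere (0.337, 0.901), cell cycle (0.833, 0.774), lysosome and autophagy (0.79, 0.781) and cholesterol synthesis (0.955, 0.94). Among cell markers they were macrophage (0.79, 0.515), neutrophil (0.866, 0.699), T and NK (0.581, 0.339), B and plasma (0.923, 0.737), adipocyte (0.79, 0.94), atrial (0.339, 0.929), erythroid (0.627, 0.515) and skeletal muscle (0.434, 0.251). At most 2 genes of any of these lists passed in 1 direction. The skeletal muscle genes Tnnt3 and Tnni2 and the interferon gene Igtp, which fell at 100 nm, were among those that did not pass without ISO replicate 2.

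No gene passed in the direct comparison of the particle sizes, and collagen genes as a group lay lower at 1 µm. edgeR called 0 genes for 1 µm against 100 nm PS, with 49 at an unadjusted p under 0.05, DESeq2 called 0 with 74 and limma voom called 0 with 684. Collagen and matrix genes had a median of -0.34 (-0.32 in batch 1, -0.61 in batch 2), with a camera adjusted p = 1.9e-15 and an adjusted p = 0.488 with an estimated correlation, and 0 of 32 genes passed, also over the list alone. Each median is followed by the camera adjusted p at the preset and then with an estimated correlation. Fatty acid oxidation (0.18, 8.9e-06, 0.606), heat shock (0.21, 8.9e-06, 0.344), sarcomere (0.16, 0.00386, 0.606), glucocorticoid response (0.29, 0.00531, 0.488) and glycolysis genes (0.11, 0.0206, 0.606) lay higher at 1 µm. Atrial (-0.25, 8.9e-04, 0.488), mesothelial (-0.61, 0.00441, 0.662), endothelial (-0.14, 0.00858, 0.606), fibroblast (-0.14, 0.012, 0.606) and Schwann markers (-0.26, 0.0184, 0.606) lay lower. When adjusted over the atrial list alone 2 of its genes were lower. The atrial list rested on 100 nm PS replicate 1, with a mean log2 CPM of 5.31 against 3.04 to 3.60 in the rest of its group. Its mean log2 fold change was -1.21, and without that library its median was -0.11 (adjusted p = 0.0741) and its mean -0.22. Also without 100 nm PS replicate 1, the mesothelial (-0.18, adjusted p = 0.175), Schwann (-0.11, 0.315), fibroblast (-0.07, 0.155), sarcomere (0.10, 0.155) and glycolysis lists (0.07, 0.155) did not pass. Leaving out 1 µm PS replicate 5 ended the calls of glycolysis (0.03, 0.54), sarcomere (0.04, 0.231), endothelial (-0.07, 0.287), fibroblast (-0.07, 0.128) and Schwann genes (-0.18, 0.114). Calls also ended for glycolysis without ISO replicate 2 (0.0855), 100 nm PS replicate 2 (0.0772) or 1 µm PS replicate 4 (0.0764), and for fibroblast markers without ISO replicate 2 (0.0677) or 1 µm PS replicate 4 (0.103). They ended for glucocorticoid response without 100 nm PS replicate 4 (0.077) or 1 µm PS replicate 6 (0.0631), and for endothelial markers without 100 nm PS replicate 5 (0.0946). For Schwann markers this was so without 1 µm PS replicate 2 (0.0605), and for mesothelial markers without 1 µm PS replicate 3 (0.433). The collagen, heat shock and fatty acid oxidation lists passed whichever library was left out. Their medians moved by over 1.5 times for collagen without 1 µm PS replicate 1 (-0.59), for heat shock without 1 µm PS replicate 5 (0.13), and for fatty acid oxidation without 1 µm PS replicate 3 (0.28), 5 (0.09) or 6 (0.11). Larger medians came for endothelial markers without 100 nm PS replicate 4 (-0.23) or 1 µm PS replicate 3 (-0.22), and for fibroblast markers without 1 µm PS replicate 1 (-0.24). The same held for Schwann markers without 100 nm PS replicate 6 (-0.40) and for mesothelial markers without 1 µm PS replicate 4 (-1.07). Genes such as Col1a1, Col3a1 and Postn, which passed at 100 nm and not at 1 µm, are therefore not shown to differ between sizes.

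Across both PS groups, matrix genes rose against ISO, and the falls of nuclear oxidative phosphorylation and ribosomal genes were smaller without ISO replicate 2. The mean of both PS groups differed from ISO in 2590 genes, 995 higher and 1595 lower, and in 1925 to 3458 without single libraries. The count was 740 after the GC correction, 709 without the batch term and 467 with the replicate number as a block. Of 32 collagen and matrix genes 20 rose, or 26 over the list alone (median 1.05, camera adjusted p = 9.0e-11, adjusted p = 0.709 with an estimated correlation). After the GC correction 3 of them rose, at a list median of 0.88. Of 71 oxidative phosphorylation genes 35 fell, or 48 over the list alone (median -0.78, camera adjusted p = 9.0e-11, adjusted p = 0.709 with an estimated correlation). The median was -0.33 (camera adjusted p = 0.00483) and 6 genes fell without ISO replicate 2, and 58 fell without ISO replicate 1 and 23 without ISO replicate 4. Of 45 ribosomal protein genes 29 fell, or 40 over the list alone (median -1.08, camera adjusted p = 3.9e-08, adjusted p = 0.784 with an estimated correlation). That median was -0.34 (camera adjusted p = 0.0978) and 1 gene fell without ISO replicate 2, and 42 fell without ISO replicate 1. All PS libraries lay within the range of the ISO libraries for the scores of both lists when the batches were pooled. In batch 2, which does not hold ISO replicate 2, ISO lay above PS for ribosomal genes (8.09 to 8.95 against 7.27 to 7.74). The same held for oxidative phosphorylation (9.29 to 9.88 against 8.61 to 8.89). In batch 1 the ribosomal scores of ISO replicates 1 and 3 (6.9 and 7.62) lay below all PS libraries (7.68 to 8.06), and only ISO replicate 2 lay above them. For oxidative phosphorylation in batch 1, PS libraries ran from 8.57 to 8.9. There ISO replicate 1 (7.96) lay below all of them, ISO replicate 3 (8.7) lay within their range and only ISO replicate 2 (10.29) lay above it. The mitochondrially encoded list was at -0.75 (camera adjusted p = 0.00438), at -0.94 without ISO replicate 2 and at -0.42 without ISO replicate 1 (camera adjusted p = 0.113). Of 33 fatty acid oxidation genes 9 fell (median -0.50, with -0.88 in batch 1 and 0.01 in batch 2), against 4 without ISO replicate 3 and 15 without ISO replicate 5. Of 16 TGF-beta and myofibroblast genes 5 rose (median 0.56), and without ISO replicate 2 it was 6, with 2 lower. Of the 41 lists 13 passed at the preset correlation and 0 with an estimated one, whose adjusted p ran from 0.709 to 0.97.

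Most genes that changed at 1 size also changed at the other, in comparisons that share the 6 ISO libraries. Among the calls, 331 genes rose at both sizes against 16.4 for independent lists, and 559 fell at both against 37.4. The log2 fold changes correlated across genes at r = 0.94 with a covariance of 0.368. The 100 simulated draws held unchanged groups that shared 1 redrawn control group. Their median r was 0.88 (0.34 to 0.97), and their median covariance 0.184 (0.0163 to 0.47). The median number of shared calls by limma's moderated test was 0, with up to 2468 within the central 95% of draws, and 11 of the 100 draws had at least the 807 of the real data by that test. The observed covariance lay within the range of no effect and 0.184 above its median. With the ISO libraries split, 3 to each comparison, the median r over 20 splits was 0.28 (0.13 to 0.46) and the covariance 0.158 (0.0765 to 0.194). With the same 3 ISO libraries in both comparisons the median r over 20 sets was 0.95 (0.77 to 0.97).

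The effect of PS differed between the sequencing batches for fatty acid oxidation genes as a list and for single clock genes. The fatty acid oxidation list was higher in batch 2 than in batch 1 relative to ISO at 100 nm (camera adjusted p = 3.9e-07, adjusted p = 0.908 with an estimated correlation) and at 1 µm (1.1e-09, 0.38). At 100 nm, where batch 2 holds 1 PS library, 1 of 41 lists passed this test at the preset correlation. At 1 µm 13 did, among them heat shock (0.0018), collagen and matrix (0.0427) and circadian clock genes (0.0401, and 0.703 with an estimated correlation). The clock list did not pass at 100 nm (0.137), and 0 lists passed with an estimated correlation at either size. For 1 µm PS, 17 genes differed in effect between batches by a batch-by-group term, with 2310 at an unadjusted p under 0.05, and all 17 had opposite signs. They included the clock genes Dbp (3.36 in batch 1, -3.07 in batch 2, adjusted p = 0.0255) and Ciart (5.60, -2.74, adjusted p = 0.0255). Others were the clock genes Nr1d2 (0.65, -2.17, adjusted p = 0.0304) and Nfil3 (-1.27, 2.02, adjusted p = 0.00469), as well as the growth factor gene Bmp4 (1.97, -0.69, adjusted p = 0.0428). For 100 nm PS, where batch 2 holds 1 library, 4 genes differed, Gm10052, Gm15429, Eif4a-ps4 and Ubb-ps, with 880 at an unadjusted p under 0.05. Across all genes the log2 fold changes of the batches correlated at r = 0.35 for 100 nm and 0.19 for 1 µm PS. Batch 1 alone gave 1134 and 598 changed genes, and batch 2 alone gave 7 and 11.

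**Figure D3:**
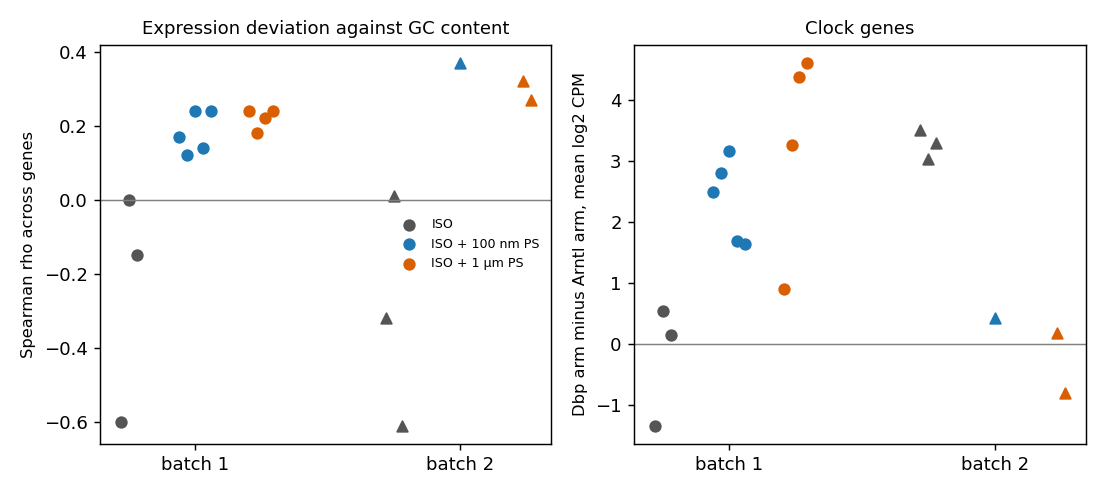
Left, the Spearman correlation across genes between GC content and the deviation from the batch mean in each of the 18 libraries by batch, coloured by group, from -0.61 to 0.01 in ISO and from 0.12 to 0.37 in PS libraries. Right, the clock score of each library (mean log2 CPM of Dbp and its partner genes minus that of Arntl and its partner genes) by batch, coloured by group, with PS above ISO in batch 1 (2.78 against -0.21) and below it in batch 2 (-0.06 against 3.28).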

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

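The tests chosen only after the result was seen were the GC correction, the thinning to equal totals, the removal of ISO replicates 1 and 2 together, the fold kept without ISO replicates 1 and 2, the comparison of matrix genes with fibroblast markers, the tests on clock genes without those called by the batch-by-group term, the tests of the clock difference and of the clock gene arms, the splits within batches, the count of calls in simulated draws, and the inclusion of Myl4 among the genes screened for outlying libraries.

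Collagen and stress genes of single libraries stood apart within their groups. In 1 µm PS replicate 1, Col1a1 was at 613 CPM (258 to 344 in the rest of its group), Col3a1 at 1070 CPM (407 to 604) and Postn at 320 CPM (29.7 to 137). In 1 µm PS replicate 5, Myh7 was at 139 CPM (43.3 to 77.4), Acta1 at 1270 CPM (174 to 395) and Atp2a2 at 14700 CPM (3550 to 6080), and its mean log2 CPM of ribosomal protein genes was 7.27 (7.74 to 7.93). In 1 µm PS replicate 6 immediate early genes had a mean log2 CPM of 4.94 (3.47 to 3.94). In 100 nm PS replicate 1, Nppa was at 2350 CPM (320 to 907) and Myl4 at 573 CPM (2.58 to 5.90), and in 100 nm PS replicate 6, Nppb was at 568 CPM (106 to 231) and Myh6 at 35200 CPM (11400 to 16000). That library is the only one of its group in batch 2, where Myh6 ran from 20600 to 54600 CPM against 6070 to 17200 CPM in batch 1, and the screen took no account of batch. ISO replicate 2 had 13152 genes detected, 4.81% of counts from mitochondrial rRNA, and mean log2 CPM of 2.20 for immediate early genes (3.24 to 3.79 in the rest of its group), 5.62 for fibroblast markers (6.11 to 6.35) and -1.04 for Schwann and neuron markers (0.83 to 1.43). ISO replicate 1 took 42.6% of its counts from mitochondrial protein-coding genes. These are 18 outlying values from 7 libraries, 5 of them from ISO replicate 2, among 93 groups of values screened, and chance gives about 1 in 20 groups. The effect of PS differed between the batches for 4 genes at 100 nm and for 17 genes at 1 µm, by the batch-by-group term, but batch 2 holds 1 library of 100 nm PS, so the 4 genes cannot be set apart from that animal.

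Many genes changed against ISO at both particle sizes, 1399 at 100 nm and 1081 at 1 µm, and genes such as Trdn (-1.23 and -1.24) and Tgfb1 (0.78 and 0.74) changed at both. Unequal depth outside mitochondrial genes was argued against (at least 89% of the calls were kept after thinning each library to 7712940 counts outside those genes), and so were ISO replicates 1 and 2 as the whole cause, since the median call kept 74.5% (100 nm) and 77.7% (1 µm) of its fold without them. That test replaced an earlier one by the calls kept, 29.7% and 51.6%, which fell on different sides of its bound of 50%. The GC correction, judged by the calls kept, left a median of 66.7% (100 nm) and 58.3% (1 µm) of the fold, also above 50%. The explanations were therefore not judged by the same measure. A GC bias between libraries stays open and may be part of the pattern: after the correction 0% of the calls were kept, their median absolute log2 fold change went from 0.84 to 0.55 at 100 nm and from 0.81 to 0.47 at 1 µm at nearly unchanged SE (0.21 and 0.21; 0.20 and 0.19), and 1050 of 1399 and 712 of 1081 calls kept an unadjusted p under 0.05. Most calls ended with smaller folds, but not all. With fewer small p values among all genes a call needs a smaller p, and the lowest adjusted p was 0.0506 and 0.0912. A simulated GC trend in 3 ISO libraries gave 0 calls, but it lay in only a part of the ISO group. It therefore cannot show how many calls a trend that separates all ISO from all PS libraries would give. Since the GC trend follows the groups, the correction also takes out any real effect that runs with GC content, and 2953 and 2349 genes still had an unadjusted p under 0.05 where chance gives 731, so a treatment effect stays open as well.

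Collagen and matrix genes lay higher in both comparisons (medians 1.27 and 0.89). GC content, length and expression level were argued against, since the list lay at percentile 100 of 10000 lists matched on them at both sizes, whose central 95% ended at 0.34 and 0.39. The matched lists hold unrelated genes, so the percentile takes no account of matrix genes varying together. ISO replicates 1 and 2 were argued against, since at least 79.3% of the median was kept without them. A larger share of fibroblasts of unchanged expression would raise matrix genes and fibroblast markers alike, if both come from fibroblasts alone. That was argued against as the whole cause for these hearts. The matrix median exceeded that of fibroblast markers, with no shared gene, by 0.90 (95% bootstrap interval 0.50 to 1.29) and 0.64 (0.28 to 0.87). The test cannot exclude a larger share of activated fibroblasts, which may hold more matrix RNA relative to these markers. The bootstrap resampled genes with the hearts held fixed, so its interval does not measure the spread between hearts. After the GC correction Col1a1 at 100 nm went from 1.86 (SE 0.50) to 1.41 (SE 0.49) and did not pass (adjusted p = 0.133), since the fold shrank at nearly unchanged SE. Postn at 100 nm went from 1.56 (SE 0.48, adjusted p = 0.0467) to 2.11 (SE 0.43, adjusted p = 0.0735), so its call ended through the adjustment and not its fold. It newly passed for the mean of both PS groups, from 1.23 (adjusted p = 0.0575) to 1.81 (adjusted p = 0.0248). Fn1 (0.85 and 0.69) and Col14a1 (1.23 and 1.23) passed before and after it for the mean of both PS groups. PS exposure stays open, and differences in dissection between hearts were not tested.

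Clock genes such as Dbp (3.36 and -3.07 at 1 µm in batches 1 and 2) moved in opposite directions in the batches. The score of Dbp and its partners minus Arntl and its partners was 2.78 ± 1.25 in PS (SD, n = 9) against -0.21 ± 0.99 in ISO (n = 3) in batch 1 (exact two-sided permutation p = 0.00455), and -0.06 ± 0.65 (n = 3) against 3.28 ± 0.24 (n = 3) in batch 2 (exact p = 0.1, the smallest possible). These differences, 2.99 and -3.34, differed between batches by 6.33 (exact permutation p = 0.000227 over 4400 permutations), but the score holds 4 genes whose opposite signs had drawn attention to it. Without those 4 (Dbp, Nr1d2, Ciart and Nfil3) the differences were 2.45 and -2.87. GC content, length and expression were then argued against (percentile 0 of 10000 matched lists in batch 2 and 100 in batch 1), and so was PS shifting the clock one way (difference 5.32, exact permutation p = 0.000909). Neither value is independent of how the pattern was chosen. The genes left include Per3 and Per2, whose batch-by-group terms at 1 µm nearly passed (edgeR adjusted p = 0.0612 and 0.0717). Both arms moved against each other across the 18 libraries, centred within batch (Pearson r = -0.70, permutation p = 0.001; Spearman rho = -0.79, permutation p = 1e-04; 100000 permutations; r = -0.60 in batch 1, -0.96 in batch 2, -0.93 without ISO replicates 1 and 2 and -0.54 without the 4 genes), as a different clock phase at collection would give. Collection times are not in the labels, so phase is a candidate explanation that stays open, as does a different effect of PS in each batch.

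Among 100 splits of the libraries into groups of the same sizes, the real one included, 1 gave as many changed genes as the real one for 100 nm PS (1399; highest other 638), 1 for 1 µm PS (1081; highest other 715) and 1 for the mean of both (2590; highest other 323). These splits did not keep the group sizes within a batch. Among 100 splits that did, again 1 gave as many in each of the 3 comparisons (highest others 197, 138 and 760). The splits argue against chance, but the simulation of unchanged groups does not exclude it for the counts at each size. By limma's moderated test, which called 1339 genes at 100 nm and 978 at 1 µm in the real data, 15 and 14 of 100 simulated draws gave as many (highest 3586 and 4684). The mean of both was not simulated. For 1 µm against 100 nm PS the real count was 0, which all 100 splits reach by definition (highest other 0), so the splits say nothing about chance there.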

How the results depend on the processing

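The alternatives chosen only after the result was seen were the removal of ISO replicates 1 and 2 together, the GC correction, the GC and length correction, the GC correction without ISO replicate 2, the same 3 controls for both sizes, and thinning.

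The direct comparison of particle sizes gave 0 genes with edgeR (49 at an unadjusted p under 0.05), DESeq2 (0; 74) and voom (0; 684) and in all other settings except batch 2 alone (1 gene). For 100 nm PS, with 1399 genes, RLE (1519) and upper-quartile factors (1462), the stricter filter (1494), voom (1735), batch 1 alone (1134), 1 surrogate variable (1941) and thinning (1420) stayed within 1.5 times. The surrogate variable moved the share of higher genes from 40.5% to 29.9% at 100 nm and from 39.1% to 29.7% at 1 µm.

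DESeq2 gave 2607 genes at 100 nm and 2322 at 1 µm, and at 1 µm voom gave 1731 and 1 surrogate variable 1790. An adjusted p under 0.1 gave 2644, 2328 and, for the mean of both, 4009. A fold change of at least 2 gave 456, 297 and 669. No filter gave 717 and 481, with more genes tested. Without the batch term edgeR called 0, 0 and 709 genes (2759 and 2358 at an unadjusted p under 0.05), for which the cause was not tested. Batch 1 alone gave 598 at 1 µm, and batch 2 alone, with fewer libraries, gave 7, 11 and 272, of which 0 at either size were among the genes called with all libraries. With only the groups compared it was 364 and 0 (2701 unadjusted at 1 µm). That fit has fewer libraries and takes no spread from the other PS group, and the cause of the lower counts was not tested. The count at 1 µm was 692 to 808 without single libraries of 100 nm PS, so it also depends on libraries outside the comparison. Without ISO replicates 1 and 2 it was 606 at 100 nm and 1543 for the mean. The GC correction gave 0, 0 and 740, and with length 31, 5 and 440. After the GC correction alone the median call kept 66.7% of its fold at 100 nm and 58.3% at 1 µm. With the replicate number as a block edgeR called 0, 0 and 467 genes (2822 and 2875 unadjusted). Among 18 pairs with the same number 3 had a correlation of deviations over 0.1 (-0.437 to 0.229), and 0 libraries were closest to their own number. No pairing by number showed in these correlations, which could miss a weak one.

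Without single libraries the counts ran from 170 to 2283 at 100 nm, from 265 to 2334 at 1 µm, from 1925 to 3458 for the mean and from 0 to 0 between sizes. The lists that passed ran from 11 to 14 (13 with all libraries) and from 9 to 13 (11). With an estimated correlation 0 and 0 lists passed, and with fry 3 and 1. The correlation of the sizes' fold changes, 0.94, was 0.28 with split controls, 3 to each size, and 0.95 (0.77 to 0.97) with the same 3 controls for both sizes, so fewer controls alone did not lower it.

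Among 149 named values, 3469 alternatives kept the side of the threshold, 1499 kept the direction only and 82 newly passed. The sign changed in 37, of which 30 were of values called in neither fit and are among the 3469, and 7 were of called values. Tnnt3 at 100 nm became 0.38 with 1 surrogate variable and ran from -3.67 to 0.18 (without ISO replicate 2) without single libraries. With 1 surrogate variable Igtp became 0.16 and Tnni2 0.01, which follow the level of ISO replicate 2 (-0.827 on that variable). After the GC and length correction mt-Nd1 became 0.02 at 100 nm and 0.18 at 1 µm, and without ISO replicates 1 and 2 Rpl6l became 0.23 at 1 µm; the cause was not tested. The GC correction ended the camera call of the mitochondrially encoded list (-0.10, -0.02) and of immediate early genes (0.27, 0.31) at both sizes, and of calcium handling (-0.19) and endothelial genes (0.34) at 1 µm. With it antigen presentation (-0.64, adjusted p = 0.0248) and sarcomere genes (-0.28, 0.0304) newly passed at 100 nm, and fibroblast (0.24, 0.0464) and skeletal muscle markers (-1.50, 0.0302) at 1 µm. With 14032257 to 22600570 counts per library depth limited little, since thinning to equal totals outside mitochondrial genes gave 1420 and 1081 genes.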

Other observations

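The GC correction, its use without ISO replicate 2, its use on the mean of both PS groups and the genes named from it were chosen only after the result was seen.

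Some nuclear genes of the ribosome and of oxidative phosphorylation were lower in PS hearts with and without the GC correction, and the falls were smaller without ISO replicate 2. For the mean of both PS groups against ISO, edgeR's quasi-likelihood test called 740 genes after the correction, 132 higher and 608 lower, and 532 of them were called in the same direction without it, 78 higher and 454 lower. Of these, 25 of 45 ribosomal protein genes and 15 of 71 nuclear genes of oxidative phosphorylation fell, and 4 of 16 TGF-beta and myofibroblast genes rose, namely Tgfb1, Tgfb3, Acta2 and Ccn2. Of 32 collagen and matrix genes Fn1 and Col14a1 (2 genes) rose in both fits, and the list's median after the correction was 0.88. The complex I gene Ndufb1 was at -2.07 (SE 0.34) before and -2.33 (SE 0.33, adjusted p = 0.0146) after, the mitochondrial ribosome genes Mrps22 at -0.78 and -0.72 and Mrpl1 at -1.18 and -0.84, and the NF-kB subunit Nfkb1 at 0.47 (SE 0.12) and 0.68 (SE 0.11, adjusted p = 0.0146). After the correction the ribosomal list had a median of -1.11 with all libraries and -0.36 without ISO replicate 2, where 1 of its genes fell and the list still passed (camera adjusted p = 8.6e-05). Without the correction and without ISO replicate 2 it was at -0.34 and did not pass (camera adjusted p = 0.0978). Oxidative phosphorylation was at -0.76 and -0.38, where 1 gene fell and the list still passed (camera adjusted p = 5.5e-07), and collagen and matrix genes were at 0.65 without that library, where 0 passed (camera adjusted p = 2.6e-13). These camera values use the preset correlation, and the estimated one was not run after the GC correction. Without the correction no list of the 41 passed with an estimated correlation (camera adjusted p from 0.709 to 0.97). The mitochondrially encoded list was at -0.06 after the correction with 1 of 13 genes lower (camera adjusted p = 0.67). No explanation of these values was tested.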
